A study of Mus musculus with 47 samples.

How the data were processed

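Total RNA from striatum, cortex and cerebellum had been hybridised to mouse Illumina bead arrays, 1 sample per array, giving 47 arrays in 12 groups of region, genotype and treatment. Groups and replicate numbers came from the sample titles. The deposited table of non-normalized intensity values held 24613 probes per array and no detection p values. Per the submitters' processing notes the authors used BeadStudio, whose version is not given in the sources used here. The deposited intensity medians of the arrays differed from 122.2 to 289.3, so those values had not been normalized between arrays. A second deposited table held log2 values of the same probes, and these differed by at most 0.0115 from quantile-normalized log2 intensities computed here, with array medians from 7.254 to 7.256, so scale, centring and direction of the authors' log2 values were known. 1 sample column of the non-normalized table matched no sample and was not used.

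The intensities were background-corrected with normexp at an offset of 50 and quantile-normalized over the 47 arrays in R 4.3.3 with limma 3.58.1. Of the probes, 20984 had 1 gene symbol in the platform annotation, 1 had several and 3628 had none. Symbols were brought up to date through gene identifiers in a reference table of assembly GRCm38.p6, used for names only, in which 20968 probes matched. For each of the 3728 genes with several probes, the probe with the highest mean log2 level over all arrays stood for the gene, and unnamed probes stayed in under their own identifier, which left 19596. A probe was tested in a region where its mean was above the 40th percentile of that region.

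Each region had its own limma fit (lmFit and eBayes) over all its arrays in 4 groups, and the comparisons of the genotype difference between regions used all 47 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 34 gene lists of cell types and pathways, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 1059 list entries 886 matched the arrays, and lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. The rule named, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, the 5 genes with the smallest p where fewer than 5 were called, up to 4 members of each list with the smallest p, and a fixed set of Huntington's disease and striatal genes, 1 of which was not on the arrays. The text gives a part of these genes. Genes called in all 3 regions, genes called with 4b only under an alternative, and the genes of the averaged 4b comparison and of the patterning families were chosen after their values were seen.

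The shift along the genotype signature used genes called for the mean of both transgenic groups against wild-type control, a choice that does not depend on which transgenic array was treated, and an exact permutation test of the 4 and 4 arrays. The gene tests and the shift were tested on simulated arrays with known changes added. Each gene was drawn independently from a normal distribution with its mean and residual SD in the region. Correlation between genes, BeadChip effects and arrays of low quality were absent, so the percentages below need not hold for the real arrays. For the genotype comparison in striatum, 94% of 50 genes changed 2-fold and 58% of 50 changed 1.5-fold were recovered among 12030 genes, and in cerebellum 80% and 48% among 12049. For 4b in transgenic mice, 92% of the 2-fold changes were recovered in striatum, 94% in cortex and 90% in cerebellum, and 76%, 70% and 52% of the 1.5-fold changes. A simulated return of 300 genes by 25 percent toward wild type gave the smallest possible exact p of 0.0286 in each region. Those genes had been changed 2-fold and varied independently, so this does not measure the power in the real arrays. In the real striatal arrays the 95% interval of the shift, from -25.7 to 26.8 percent, did not exclude such a return.

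Array identities held up: the expression of the Y-linked gene Eif2s3y matched the labelled sex on 47 of 47 arrays, no pair of arrays was identical, and replicates of a group correlated at 0.964 to 0.994. A dimmer Y-linked gene, Kdm5d, did not separate the sexes fully. It was at 6.42 in the male 4b-treated transgenic striatum 2 and at 6.56 in the female 4b-treated transgenic cortex 4. The arrays came from 6 BeadChips. In control mice the genotypes shared no BeadChip in striatum and cortex and shared 1 in cerebellum. Alternatives covered the background correction, the normalization, the filter, the choice of probes, an intensity trend, array weights, the arrays in the fit, the BeadChip as a fixed and as a random block, sex, the replicate number and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.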

Results

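RNA from the striatum, cortex and cerebellum of R6/2(300Q) transgenic mice and wild-type mice was measured on Illumina bead arrays. The transgene carries a fragment of human huntingtin with an expanded glutamine repeat, and the mice are a model of Huntington's disease. Mice of both genotypes received either 4b, an inhibitor of histone deacetylases given at 1 mg/ml in place of drinking water for 67 days from 4 months of age, or a control treatment. The 47 arrays formed 12 groups of 4, except that wild-type control cerebellum had 3. The labels name replicates without saying that each came from a separate animal, so p-values measure the spread between these samples. The median intensity per array lay between 122.2 and 289.3, and the number of arrays limited the precision.

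The first question was which genes differed between transgenic and wild-type striatum without 4b. Genes that define the medium spiny neuron, the main neuron of the striatum, were lower in transgenic mice. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, fell from 13.28 ± 0.07 (SD, n = 4) on the log2 scale in wild-type to 12.26 ± 0.16 (SD, n = 4) in transgenic mice, a 2.03-fold decrease (limma adjusted p = 1.1e-04). Penk, the precursor of enkephalin, was 2.13-fold lower (11.43 ± 0.35 against 10.34 ± 0.17, SD, n = 4 each, limma adjusted p = 0.0015). Drd2, the dopamine receptor of the indirect pathway, was 1.96-fold lower, and Drd1, the receptor of the direct pathway, 1.51-fold lower. The largest rise was that of Wt1, a zinc finger transcription factor of kidney and gonad development, from 6.81 ± 0.36 to 9.31 ± 0.34 (SD, n = 4 each), or 5.65-fold (limma adjusted p = 1.8e-05). The wild-type level of Wt1 lay close to the background, where probes for Y-linked genes in female arrays reached 6.75, so this fold has no exact size.

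Of the 29 medium spiny neuron genes measured in striatum, 14 fell and none rose when adjusted over all genes, and 19 fell when adjusted over the list alone. Their median log2 difference was -0.48, and among the 14 were Cnr1, the cannabinoid receptor CB1 (-0.97), and Pde10a, the striatal cyclic nucleotide phosphodiesterase (-0.94). The list was lower than the other genes by camera (adjusted p = 1.5e-17), with adjusted p = 0.022 when the correlation between its genes was estimated. Pdyn, the precursor of dynorphin, had a difference of -0.48 that did not pass (limma adjusted p = 0.061). The huntingtin gene itself, Htt, differed by -0.03 and did not pass.

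**Figure D1:**
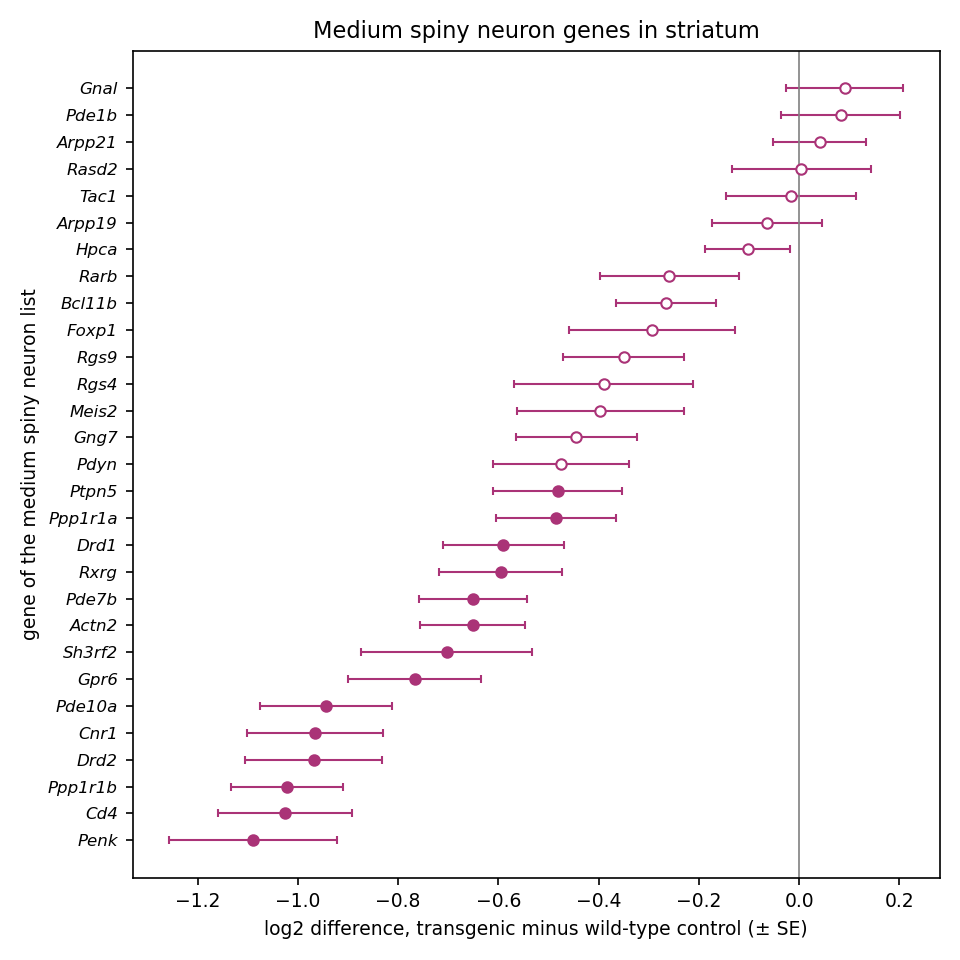
Log2 difference (transgenic minus wild type, control mice, n = 4 arrays each) of the 29 medium spiny neuron genes in striatum, with the standard error as bars and filled points for adjusted p under 0.05. Filled points mark 14 genes, all lower, and 25 of the 29 lay below 0.

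Other groups were also lower in transgenic striatum. Of 25 astrocyte genes 6 fell (12 lower and 1 higher when adjusted over the list alone), among them Slc1a2, the glial glutamate transporter (-0.75), and Gstm1, a glutathione transferase (-0.49), and the camera adjusted p of 5.2e-08 became 0.022 with an estimated correlation. Of 35 calcium signaling genes 4 fell (7 when adjusted over the list alone), among them Ryr1, a calcium release channel (-1.76, from 9.86 ± 0.46 to 8.09 ± 0.11, SD, n = 4 each), and Camkk2, a calcium-dependent kinase (-0.45). That list had a camera adjusted p of 4.8e-06 and an adjusted p of 0.032 with an estimated correlation. Of 24 glutamate receptor and scaffold genes 7 fell (8 when adjusted over the list alone), including Shank3, a scaffold of excitatory synapses (-0.68), but the camera adjusted p of 4.2e-06 was not kept (adjusted p = 0.111 with an estimated correlation). Of 17 circadian clock genes 4 fell (6 when adjusted over the list alone), including Bhlhe40 (-0.52), Rorb (-0.54) and Npas2 (-0.50), which are transcription factors of the clock, with camera adjusted p = 0.0018 and adjusted p = 0.135 with an estimated correlation. Both genes that mark cholinergic neurons by making and loading acetylcholine fell, Chat by 0.47 and Slc18a3 by 0.56 on the log2 scale (2 of 6 on the list, 4 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.180 with an estimated correlation).

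Genes outside these lists gave the other large differences in striatum. Ddit4l, an inhibitor of mTOR signaling, was 4.01-fold lower (11.34 ± 0.24 against 9.34 ± 0.32, SD, n = 4 each, limma adjusted p = 7.5e-05). Irx5 and Nkx6-1, homeobox transcription factors of embryonic patterning, rose by 1.37 and 1.04 on the log2 scale, and the wild-type level of Nkx6-1 lay within the background, where probes for Y-linked genes in female arrays reached 6.75. Hdac1, a histone deacetylase and so a member of the class of enzymes that 4b inhibits, rose 1.48-fold, from 8.98 ± 0.03 to 9.55 ± 0.05 (SD, n = 4 each), while Hdac3 differed by 0.13 and did not pass (limma adjusted p = 0.45). Of 22 interferon and antigen presentation genes 19 had a positive difference, with a list median of 0.42, and 2 rose when adjusted over all genes and 11 when adjusted over the list alone (camera adjusted p = 4.6e-06, adjusted p = 0.180 with an estimated correlation). The astrocyte marker Gfap (-0.04) and the microglia marker Aif1 (-0.42) did not pass.

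In all, 455 of 12030 genes differed in striatum, 173 higher and 282 lower, with a median fold of 1.45 (limma, Benjamini-Hochberg). The groups shared no BeadChip, and with the BeadChip as a fixed block over all 47 arrays 690 genes were called, 314 of them among the 455. That fit also took its spread from all 47 arrays, so its count does not show the effect of the BeadChip alone. The block counts given below for cortex, cerebellum and 4b within a region came from fits of the same kind. Array weights gave 897, and leaving out transgenic control 1 gave 243, transgenic control 2 gave 281, wild-type control 1 gave 289 and wild-type control 4 gave 284. Without wild-type control 2, whose choroid plexus genes averaged 9.95 against at most 8.03 on the other arrays of its group, 560 were called.

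In cortex, the same question gave a set of developmental transcription factors as the largest rises. Hoxb5, a homeobox gene of hindbrain and spinal cord patterning, went from 6.58 ± 0.17 to 9.98 ± 0.51 (SD, n = 4 each), or 10.6-fold higher in transgenic mice (limma adjusted p = 6.5e-08). Twist1, a mesoderm factor, rose 5.39-fold (7.40 ± 0.10 against 9.83 ± 0.29, SD, n = 4 each, limma adjusted p = 3.4e-08), Tal1, a blood cell factor, by 2.31, and Barx1, Shox2 and En2, homeobox genes, by 2.29, 2.06 and 1.66 on the log2 scale. The wild-type levels of Hoxb5, Barx1 and Shox2 lay within the background of the arrays, where probes for Y-linked genes in female arrays averaged 6.27 (SD 0.20) and reached 6.75, so these folds have no exact size. Among the largest falls were Plk5, a polo-like kinase of neurons (-1.98), Cartpt, the precursor of the CART peptide (-1.15), and Ppp1r1b (-1.14).

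Astrocyte genes moved most as a group in cortex: 14 of 25 fell and none rose when adjusted over all genes, and 18 fell and 1 rose when adjusted over the list alone, with a median of -0.46. Among them were Slc1a2 (-0.87), Glul, the glutamine synthetase (-0.72), and Slc7a10, an amino acid transporter of astrocytes (-0.98). The camera adjusted p was 1.7e-12, and 0.0017 with an estimated correlation. Of 23 cortical excitatory neuron genes 7 fell (9 when adjusted over the list alone), including Camk2a, a kinase of synaptic plasticity (-0.57), and Lamp5 (-0.84), with camera adjusted p = 6.1e-08 and adjusted p = 0.0088 with an estimated correlation. Of 36 calcium signaling genes 6 fell (6 when adjusted over the list alone), among them Itpka, which phosphorylates inositol trisphosphate (-0.58), with camera adjusted p = 1.1e-05 and adjusted p = 0.0071 with an estimated correlation.

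Other cortical lists passed camera with the preset correlation alone. Of 24 interferon and antigen presentation genes 6 rose (10 when adjusted over the list alone), including Ifi27l2a (1.63), Gbp3 (1.00) and Bst2 (0.95), all induced by interferon, with camera adjusted p = 6.9e-06 and adjusted p = 0.10 with an estimated correlation. Of 18 cholesterol synthesis genes 4 fell (7 when adjusted over the list alone), including the pathway enzymes Mvd (-0.56) and Dhcr7 (-0.42), with camera adjusted p = 3.1e-05 and adjusted p = 0.085 with an estimated correlation. Of 14 GABAergic interneuron genes 2 fell, the neuropeptides Npy (-0.54) and Sst (-0.47), with 4 lower when adjusted over the list alone, camera adjusted p = 4.1e-04 and adjusted p = 0.085 with an estimated correlation. Of 24 medium spiny neuron genes 4 fell in cortex (8 when adjusted over the list alone), including Ppp1r1b and Pdyn (-0.78), with camera adjusted p = 7.8e-06 and adjusted p = 0.111 with an estimated correlation. Bdnf, the neurotrophin that cortex supplies to striatum, differed by -0.36 and did not pass (limma adjusted p = 0.18).

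In all, 614 of 12052 genes differed in cortex, 190 higher and 424 lower, with a median fold of 1.40 (limma, Benjamini-Hochberg). The groups shared no BeadChip, and with it as a fixed block 419 genes were called, 258 of them among the 614. Leaving out transgenic control 1 gave 379, transgenic control 4 gave 376 and wild-type control 4 gave 379.

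In cerebellum, fewer genes passed the test between genotypes. Cdkn2b, an inhibitor of the cell cycle, rose 3.29-fold in transgenic mice, from 8.17 ± 0.23 (SD, n = 3) to 9.89 ± 0.13 (SD, n = 4; limma adjusted p = 5.4e-04). Scn11a, a voltage-gated sodium channel, rose 2.61-fold from 6.68 ± 0.14 (SD, n = 3) to 8.06 ± 0.04 (SD, n = 4), a fold with no exact size because the wild-type level lay below the highest background probe (6.75). Igfbp5, which binds insulin-like growth factors, was 3.60-fold lower, and Plk5 2.81-fold lower (12.59 ± 0.17, SD, n = 3, against 11.10 ± 0.07, SD, n = 4; limma adjusted p = 6.8e-06). Hdac1 differed by 0.48 and did not pass in this region (limma adjusted p = 0.14).

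Of 29 oligodendrocyte and myelin genes in cerebellum 4 fell (14 when adjusted over the list alone), among them Fa2h, which makes the hydroxylated lipids of myelin (-0.94). The list median was -0.49, with camera adjusted p = 7.5e-16 and adjusted p = 0.115 with an estimated correlation. Of 16 Purkinje cell genes 1 fell (5 when adjusted over the list alone), with a median of -0.25, camera adjusted p = 7.2e-05 and adjusted p = 0.131 with an estimated correlation. Blood cell genes had a median of -1.26 and choroid plexus genes of -0.39 in the same comparison, with none of 11 and none of 21 members passing and an adjusted p of 0.290 and 0.396 with an estimated correlation.

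In all, 83 of 12049 genes differed in cerebellum, 40 higher and 43 lower (limma, Benjamini-Hochberg). The sign was the same for all 83 on the BeadChip that held both groups, but it held 1 array of each, and both had been used to call the genes. The count was 3 with the arrays of the compared groups only, 276 with the BeadChip as a block (68 of them among the 83), 54 with median scaling, 49 with array weights, 135 without wild-type control 2, 24 without wild-type control 4 and 42 without transgenic control 4. Plk5, Cdkn2b and Scn11a were called in every alternative run for them.

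**Figure D2:**
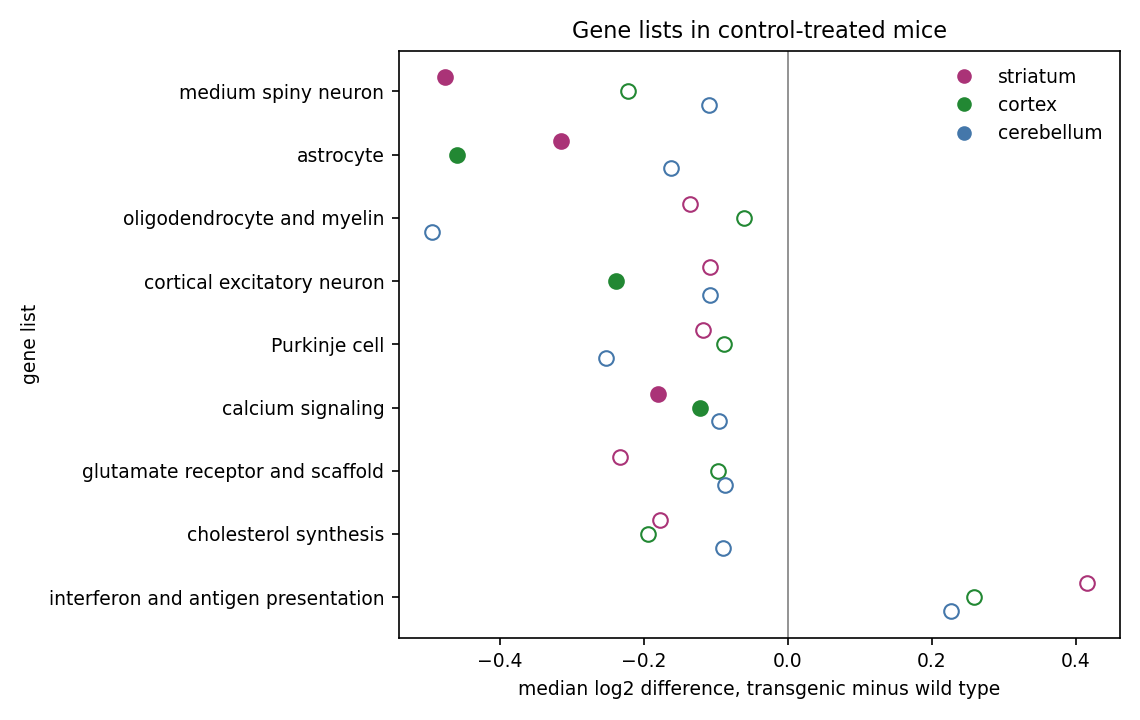
Median log2 difference (transgenic minus wild type, control mice) of the members of 9 gene lists in the 3 regions, with filled points where camera with an estimated correlation gave an adjusted p under 0.05. Filled points are medium spiny neuron, astrocyte and calcium signaling genes in striatum and astrocyte, cortical excitatory neuron and calcium signaling genes in cortex.

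Several genes differed in all 3 regions, named here because they passed in each. Celf5, an RNA-binding protein, was higher by 1.16 in striatum, 1.11 in cortex and 0.63 in cerebellum. Hexim1, an inhibitor of transcription elongation (0.94, 0.61 and 0.87), Cbx8, a Polycomb protein (0.52, 0.39 and 0.81), Fbl, a nucleolar methyltransferase (0.46, 0.53 and 0.69), and Cdkn2b were also higher. Acss1, a mitochondrial acetyl-CoA synthetase (-0.59, -0.67 and -0.56), Igfbp5 and Plk5 were lower, and 2 unnamed probes were higher. Striatum and cortex shared 51 genes that rose, where independent lists would share 2.70, and 100 that fell, against 9.19, with none called in opposite directions. The labels do not say whether regions came from the same mice, and if they did, the lists were not independent and the p-values between regions do not hold exactly.

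The design also asks whether the genotype difference itself differed between regions. Against cortex, the striatal difference was greater for Wt1 by 2.16 and Tnnt2, a troponin, by 1.12, and lower for Twist1 (-2.22), Tal1 (-2.21), Pde10a (-1.14) and Il17rc, an interleukin receptor subunit (-1.22). In all, 25 of 11658 genes passed, 10 higher and 15 lower (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 566, where about 582.9 would arise by chance, so no broad excess was seen. Against cerebellum, 104 of 11501 genes passed, 35 higher and 69 lower, with 1234 at an unadjusted p under 0.05, where about 575.05 would arise by chance. There the striatal difference was greater for Irx5 (1.66) and Tnnt2 (1.25). It was lower for Ddit4l (-1.68), Tesc, a calcium-binding protein (-1.50), Ryr1 (-1.40), Scn11a (-1.45), which rose in cerebellum, and Pde10a (-1.27). Of 24 medium spiny neuron genes 3 were lower against cortex (4 when adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.567 with an estimated correlation). Against cerebellum 3 were lower and 1 higher (8 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.486 with an estimated correlation).

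Those cross-region counts moved with the setting. Against cortex, median scaling gave 4 higher and 13 lower, the compared groups alone gave 6 genes, the BeadChip block 12, array weights 69, no filter on dim probes 39, a stricter filter 13, and leaving out wild-type control cortex 3 gave 16. Against cerebellum, array weights gave 42 higher and 36 lower, so the excess of lower calls did not hold there, the compared groups alone gave 28, the BeadChip block 68, leaving out transgenic control striatum 2 gave 68 and leaving out wild-type control cerebellum 2 gave 318.

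The next question was what 4b changed in transgenic mice. In striatum none of the genes lowered by the transgene passed: Ppp1r1b differed by 0.12 and Penk by -0.11 between 4b and control, and Drd1 by -0.12. The smallest p in striatum belonged to genes such as Lcn2, a secreted iron-binding protein of inflammation (1.94), and Vwf, a clotting factor made by endothelium (0.60), and in cortex Lrg1, a plasma glycoprotein, had 0.82, none of which passed. In cerebellum Ccdc3, which encodes a secreted protein and was 2.28-fold lower in transgenic mice, was at 9.83 ± 0.22 in control and 10.83 ± 0.25 in 4b-treated transgenic mice (SD, n = 4 each), a difference of 1.00 that did not pass (limma adjusted p = 0.128).

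The number of genes passing in transgenic mice was 0 of 12030 in striatum, 0 of 12052 in cortex and 0 of 12049 in cerebellum by limma, with 305, 257 and 560 at an unadjusted p under 0.05, where about 601.5, 602.6 and 602.45 would arise by chance. The alternatives gave 0 in striatum and cortex throughout. In cerebellum they gave 2 with array weights (Apoc1, an apolipoprotein, and Ccdc3), 38 with the compared groups only (35 higher and 3 lower), 2 with the BeadChip block (Car12 and Clic6) and 35 without transgenic control 1 (2 higher and 33 lower). The 38 held 11 members of the choroid plexus list, all higher, such as Kl (3.47), Folr1 (2.91) and Aqp1 (2.75), while the 35 held none and shared 1 gene, Ccdc3, with the 38.

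Among the fixed lists, glucocorticoid response genes had positive median differences with 4b in transgenic striatum (0.18), cortex (0.18) and cerebellum (0.28), with 21 of 23 members positive in striatum. None of these members passed over all genes, 1 passed in striatum and 1 in cortex when adjusted over the list alone, and the camera adjusted p of 6.4e-05, 8.8e-05 and 9.3e-04 became 0.721, 0.699 and 0.544 as adjusted p with an estimated correlation. Interferon and antigen presentation genes had a median difference of -0.17 with 4b in striatum and -0.14 in cortex, with none passing over all genes and 2 lower in cortex when adjusted over the list alone. Their camera adjusted p of 6.4e-05 and 2.4e-06 became 0.721 and 0.544 as adjusted p with an estimated correlation. Choroid plexus genes had a positive difference for 21 of 21 members in transgenic cerebellum (median 1.18), such as Clic6, a chloride channel protein, at 8.90 ± 0.37 against 11.82 ± 0.45 (SD, n = 4 each), and 16 passed when adjusted over the list alone but none over all genes, where 11 passed with the compared groups only and 1, Clic6, with the BeadChip block. The camera adjusted p of 1.5e-26 became an adjusted p of 0.323 with an estimated correlation, and in transgenic striatum the same list had a median of -0.49 (adjusted p = 0.721 with an estimated correlation).

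**Figure D3:**
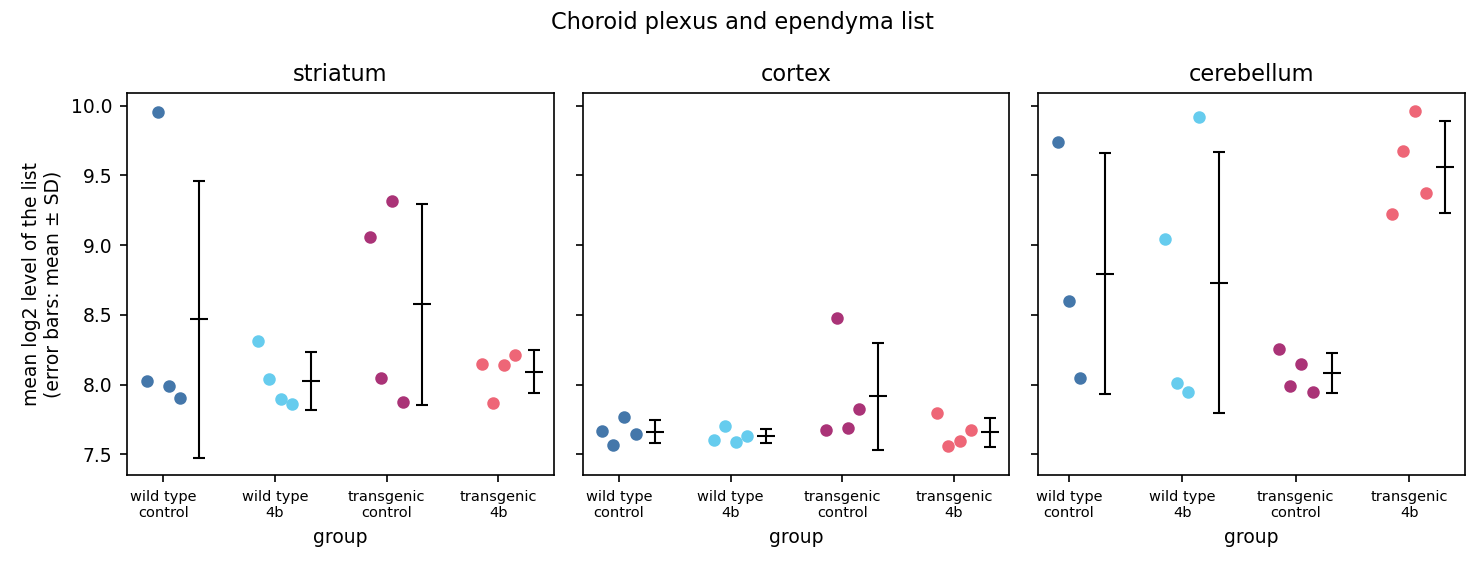
Mean log2 level of the choroid plexus and ependyma genes on each array by group in the 3 regions, with the mean and SD as bars. In cerebellum the 4 arrays of 4b-treated transgenic mice averaged 9.56 and the 4 of control transgenic mice 8.09.

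In wild-type mice, Lcn2 in striatum went from 6.47 ± 0.24, within the background, to 8.73 ± 0.51 with 4b (SD, n = 4 each), a difference of 2.26 that did not pass over all genes, and Vwf differed by 0.66. In cortex the smallest p belonged to Elmod1 (0.48) and Atp6ap2, a subunit associated with the vacuolar proton pump (0.45), and in cerebellum to Per2, a core component of the circadian clock (-0.92, limma adjusted p = 0.367). Oligodendrocyte genes had a median of -0.25 with 4b in striatum, with none of 29 passing over all genes or when adjusted over the list alone (camera adjusted p = 1.8e-11, adjusted p = 0.328 with an estimated correlation). By limma 0 genes passed in each region, with 400, 1098 and 1079 at an unadjusted p under 0.05. About 601.5, 602.6 and 602.45 would arise by chance, so cortex and cerebellum had more than that and striatum fewer. The alternatives gave 0 in cortex, at most 1 in striatum, Lcn2 with the compared groups only (limma adjusted p = 0.0085) or without 4b-treated transgenic striatum 4 (limma adjusted p = 0.0068). In cerebellum they gave 3 with the compared groups only, 96 with the BeadChip block (55 higher and 41 lower), 3 without wild-type control 2 and 35 without transgenic control 1 (10 higher and 25 lower), which is outside the compared groups but shares the estimate of the spread.

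The interaction of genotype and 4b tests whether the 4b difference itself differed between transgenic and wild-type mice. The smallest p belonged to Tmcc3 (0.58) and Slitrk3 (-0.60) in striatum, Zfp955a (-0.74) and Atp6ap2 (-0.58) in cortex, and Prune1 (-0.57) and Ntn4, a netrin (1.08), in cerebellum, and none passed. By limma 0 genes passed in each region, with 243, 791 and 383 at an unadjusted p under 0.05, and the alternatives gave 0 throughout. About 601.5, 602.6 and 602.45 would arise by chance.

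A last comparison asked whether 4b moved the transgenic profile as a whole toward wild type. Genes that differed between the transgenic groups together and wild-type controls were taken, 1050 in striatum, 1064 in cortex and 264 in cerebellum, and each array was scored by its mean signed log2 distance from wild-type control. This choice tends to miss genes that 4b brings back. With 300 simulated genes the signature held 275, 273 and 258 genes at no return, but 230, 258 and 160 at a return of 50 percent. In striatum the score was 0.472 ± 0.058 in control and 0.493 ± 0.051 in 4b-treated transgenic mice (SD, n = 4 each), a shift of 0.02 (exact two-sided permutation p = 0.571) with a 95% interval from -25.7 to 26.8 percent of the control score. In cortex the scores were 0.454 ± 0.050 and 0.457 ± 0.040 (exact p = 0.943, interval from -22.6 to 20.1 percent), and in cerebellum 0.629 ± 0.050 and 0.655 ± 0.040 (exact p = 0.429, interval from -11.4 to 22.7 percent; SD, n = 4 each). The smallest p these 70 relabelings can give is 0.0286. In 4b-treated wild-type mice the scores were 0.063 ± 0.028, 0.096 ± 0.014 and 0.151 ± 0.038 (SD, n = 4 each), each array above every wild-type control, but the genes were chosen against those controls, whose mean is the zero of the score and of the percentages, so this is no test of 4b. Within BeadChips that held both groups the shift was -0.12 in striatum, 0.01 and 0.05 in cortex and 0.07 in cerebellum, and with BeadChip effects removed it was -0.02, -0.01 and 0.02. The values within BeadChips rest on 1 array of each group, except the 0.01, which rests on 1 with 4b and 2 controls.

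**Figure D4:**
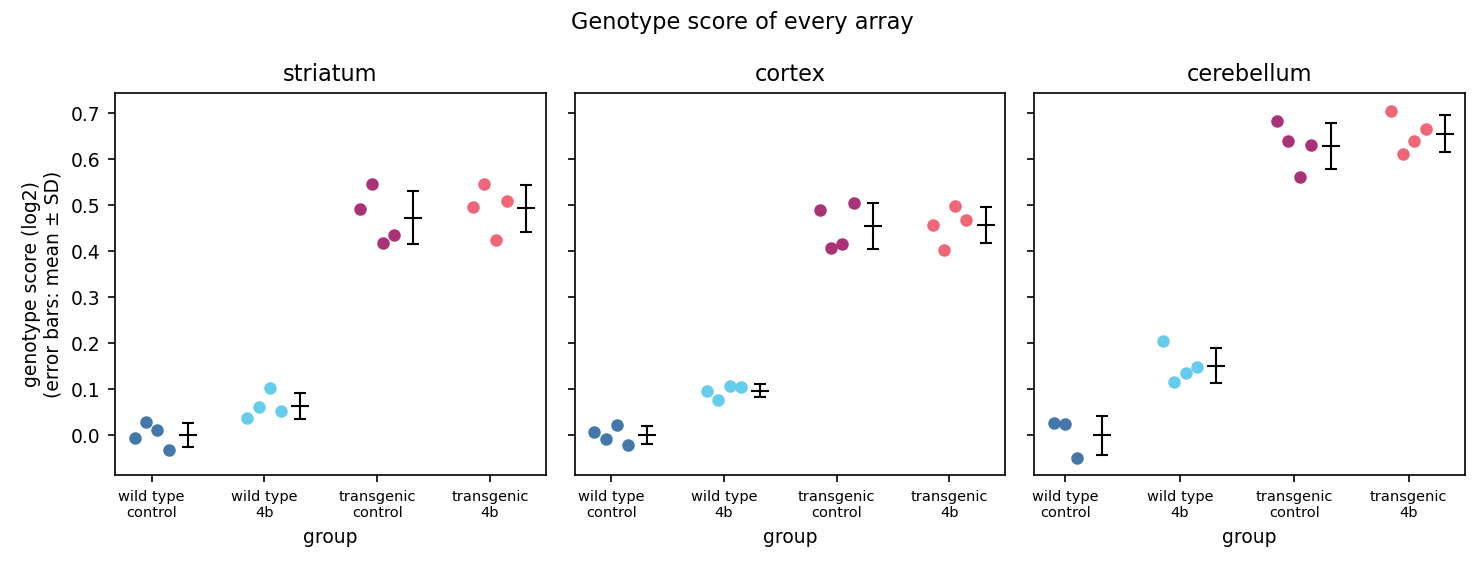
Genotype score of each array (mean signed log2 distance from wild-type control over the signature genes of the region) by group in the 3 regions, with the mean and SD as bars. The scores of control and 4b-treated transgenic arrays overlapped in each region, with means of 0.472 and 0.493 in striatum.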

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

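Both tests of the choroid plexus pattern were chosen after the result was seen, while the comparisons between regions and the search for arrays that stood apart were not.

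The genotype difference was tested directly between regions. Against cortex 25 genes differed. The transgenic rise was greater in striatum for Wt1, a developmental zinc finger factor (2.16), Tnnt2, a troponin (1.12), and 1700016K19Rik (1.09), and Plk5, which fell in both regions, differed by 0.96 because it fell less in striatum. The genotype difference (transgenic minus wild type) was lower in striatum than in cortex for Twist1 (-2.22) and Tal1 (-2.21), factors of mesoderm and blood, which rose by 2.43 and 2.31 in cortex. It was also lower for Phex, a peptidase (-1.23), Il17rc, an interleukin receptor subunit (-1.22), Pde10a, the striatal phosphodiesterase (-1.14), Cnr1, the CB1 receptor (-0.95), and Actn2, an actin-binding protein (-0.85). Of these, the calls of 1700016K19Rik, Cnr1 and Plk5 were kept in 4, 6 and 10 of 16 leave-one-out fits. Of 100 splits of the arrays 7, the real one included, called at least as many genes, which did not exclude chance, but splits of this kind can add real genotype differences and so do not count chance alone. The highest other split called 519, and a count several times the real one points to a structure of the samples: that split turned the genotype labels of all 8 striatal arrays over, so that the genotype differences of the regions added up in it.

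Against cerebellum 104 genes differed. The signed genotype difference in striatum minus that in cerebellum was positive for Irx5, a homeobox gene (1.66), Pcdh20, a protocadherin (1.64), Cpne6, a calcium-dependent membrane protein (1.52), Tnnt2 (1.25) and Rasd2, a striatal small GTPase (1.18). It was negative for Ddit4l, an inhibitor of mTOR signaling (-1.68), Tesc (-1.50), Scn11a, a sodium channel (-1.45), Ryr1, a calcium release channel (-1.40), Pde10a (-1.27), Actn2 (-0.80) and Penk, the enkephalin precursor (-0.77). These values do not say which region changed: Rasd2 and Scn11a, for example, were called between genotypes in cerebellum. The calls of Penk and Cpne6 were kept in 5 and 8 of 15 leave-one-out fits. Of 100 splits 16 called at least as many, with the same limit on what they say about chance. The highest other split called 616, and it turned 6 of 8 striatal genotype labels over, which is again a structure of the samples.

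Single arrays stood apart from the other 3 of their group in 11 of 162 groups tested, where chance gives about 8.1. Wild-type control striatum 2 had a choroid plexus score of 9.95 where the others had 7.91 to 8.03, and a median intensity of 213.6 against 122.2 to 132. The median intensity of 4b-treated wild-type cerebellum 2 was 219.1, against 134.8 to 143.7. For Penk, 4b-treated transgenic striatum 3 had a log2 level of 10.67 and 4b-treated wild-type striatum 2 of 11.05. For Pdyn, the dynorphin precursor, 4b-treated transgenic striatum 3 had 11.59, and for Cnr1 4b-treated wild-type striatum 1 had 9.29. Gfap, the astrocyte filament, was at 9.79 in transgenic control striatum 1, and Ppp1r1b, DARPP-32, at 9.40 in 4b-treated wild-type cortex 4. Htt was at 8.52 in transgenic control cerebellum 3 and Hdac3, a histone deacetylase, at 11.70 in 4b-treated transgenic cerebellum 2.

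Choroid plexus genes, which mark the tissue that makes cerebrospinal fluid and lines the ventricles next to the dissected regions, averaged 9.56 ± 0.33 in 4b-treated and 8.09 ± 0.14 in control transgenic cerebellum (SD, n = 4 each), a difference of 1.47 (exact permutation p = 0.0286, the smallest possible). In wild-type cerebellum the score was 8.73 ± 0.94 with 4b (SD, n = 4) and 8.80 ± 0.87 without (SD, n = 3), and this exact permutation p of 0.943 shows neither an effect of 4b nor its absence, so 4b treatment in transgenic mice stays open. Unequal amounts of choroid plexus in the pieces may also account for the difference: the genes varied together within groups in striatum, with a mean pairwise correlation of 0.70 and a within-group SD of the score of 0.69, and in cerebellum (0.716 and 0.68), but in cortex the correlation was 0.251 and the SD 0.25. A first version of that test used 5 hand-picked genes in place of the whole list and came out in favour of unequal dissection, and it was replaced by the list as written in its prediction. The cortical values decide little, because the list was dim there. Of 23 members on the arrays 15 passed the filter in cortex, against 21 in cerebellum. Transgenic control cortex 2 scored 8.48, and the other arrays of its group 7.67 to 7.83. These explanations cannot be told apart, since choroid content was not recorded and the wild-type arrays spread widely, with one wild-type control at 9.74.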

How the results depend on the processing

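The choroid plexus score as a covariate, leaving out single arrays outside the compared groups, which share the estimate of the spread, and leaving out the arrays of weight under 0.5 (wild-type control striatum 2 and transgenic control cerebellum 1) were alternatives chosen after seeing the data. No named gene or list past its threshold changed direction. The excess of lower calls in striatum against cerebellum did not hold with array weights. The 4b shift, which did not differ from 0, changed sign with BeadChip effects removed in striatum (-0.02) and cortex (-0.01), with median scaling in cortex (-0.0014) and without some single arrays in cortex and cerebellum. Of 5071 refits of the 215 calls of named genes, 4435 kept the call, as did 3218 of 3498 refits of list tests their side of the threshold; 46 of 67 named calls in striatum, 52 of 71 in cortex and 12 of 28 in cerebellum held without any single array of the compared groups. List tests passing fell from 102 of 438 to 6 with an estimated correlation and 35 with fry.

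Genotype in striatum called 455 genes, with array weights 897, with the BeadChip block 690, and without single arrays 243 to 560 (transgenic control 1 243, 2 281; wild-type control 1 289, 4 284). Genotype in cortex called 614, without single arrays 376 to 630 (transgenic control 4 376, 1 379; wild-type control 4 379). Genotype in cerebellum called 83, with median scaling 54, array weights 49, the compared groups only 3, the BeadChip block 276, and without single arrays 24 to 135 (wild-type control 4 24, 2 135; transgenic control 4 42). Striatum against cortex called 25, without the filter 39, with a stricter filter 13, array weights 69, the compared groups only 6, the BeadChip block 12, and without single arrays 16 (wild-type control cortex 3) to 31. Striatum against cerebellum called 104, with the compared groups only 28, the BeadChip block 68, and without single arrays 68 (transgenic control striatum 2) to 318 (wild-type control cerebellum 2).

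4b in transgenic cerebellum called 0 by limma (560 at unadjusted p under 0.05), with array weights 2, the BeadChip block 2, the compared groups only 38 (35 higher, 11 of them choroid plexus genes), and without single arrays 0 to 35 (transgenic control 1, the array of low weight; 33 lower, 1 gene shared with the 38). 4b in wild-type cerebellum called 0 by limma (1079 unadjusted), with the compared groups only 3, the BeadChip block 96, and without single arrays 0 to 35 (wild-type control 2 3; transgenic control 1, outside the compared groups and the array of low weight, 35). 4b in wild-type striatum called 0 by limma (400 unadjusted) and 1, Lcn2, with the compared groups only or without 4b-treated transgenic striatum 4 (without single arrays 0 to 1). The cause of these moves was not tested. The compared groups alone leave fewer arrays for the spread, and for transgenic cerebellum they leave out the wild-type arrays. The choroid plexus score had an SD of 0.94 with 4b and 0.87 without in wild-type cerebellum, against 0.33 and 0.14 in transgenic cerebellum. For the interactions the compared groups alone equal the reported fit, so that alternative was not run there.

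Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at a mean of 0.02 in striatum, -0.02 in cortex and 0.01 in cerebellum, and over 0.1 in 5 of 24, 5 of 24 and 4 of 21 pairs. The replicate block called 486, 576 and 58 genes for genotype in the 3 regions, 23 and 107 between regions, and 0 for 4b and the interactions. Without single arrays the 4b shift ranged from 0.0015 to 0.056 in striatum, -0.011 to 0.022 in cortex and -0.011 to 0.047 in cerebellum. Probes near the array background, where Y-linked probes in female arrays reached 6.75, give compressed differences.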

Other observations

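The genotype comparison in 4b-treated mice, the averaged 4b comparison and all tests on them were chosen after the results were seen, as were the patterning families and the tests on them, except the tests of single arrays, of background correction and of the splits of the arrays, whose bounds were set first.

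Transgenic and wild-type mice were also compared after 4b, where the genotypes shared BeadChips. In 4b-treated striatum 543 genes differed, 190 higher and 353 lower, and 451 of the 455 genes called in control mice had the same sign, 264 of them called again. In cortex 665 differed, with the same sign for 592 of 614 and 299 called again, and in cerebellum 174, with the same sign for 82 of 83 and 40 called again. The median size of the genes called in control mice was 0.53 there and 0.46 after 4b in striatum, 0.48 and 0.36 in cortex and 0.76 and 0.50 in cerebellum, but genes chosen by their size in control mice come out smaller in any second comparison. Within the BeadChip that both 4b-treated genotypes shared, the sign was the same for 446 of 455 genes in striatum, and for 552 and 582 of 614 on the pair of BeadChips in cortex and 82 of 83 in cerebellum. Few arrays stood behind these: 1 transgenic and 2 wild-type in striatum, 1 and 1 and then 2 and 1 in cortex, and 2 and 2 in cerebellum. Of 35 splits of the 4b-treated arrays only the real one called as many genes in each region, with a highest other of 5 in striatum, 2 in cortex and 3 in cerebellum, so chance was excluded.

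For the control mice, too, only the real split of 35 called as many genes, 455 in striatum, 614 in cortex and 83 in cerebellum, against a highest other of 4, 3 and 69. A share of 1 of 35, the smallest possible, lay under the bound of 0.05, but in cerebellum the next split was close. In striatum and cortex the real split also divided the BeadChips, so it does not tell genotype from BeadChip. The split with 69 exchanged transgenic control 1 for wild-type control 4 in cerebellum. For 4b in transgenic mice all 35 splits called as many as the real 0 in each region, with a highest other of 43 in striatum, 51 in cortex and 5 in cerebellum, and in wild-type mice all 35, with 1, 9 and 38. For the interactions all 100 splits did, with 3, 52 and 7, but with a real count of 0 every split calls as many by construction, so these splits decide nothing about chance. What set apart the splits with many calls was not tested. The counts of 0 by limma stood beside 305, 257 and 560 genes at unadjusted p under 0.05 in transgenic mice and 400, 1098 and 1079 in wild-type mice.

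Averaged over both genotypes and the 3 regions, 10 of 11327 genes differed with 4b, 8 higher and 2 lower (limma; 1127 at unadjusted p under 0.05), and 4 were called with the BeadChip as a block. The strongest were Vwf, a clotting factor made by endothelium (0.62, adjusted p = 1.0e-05), Lrg1, a plasma glycoprotein of inflammation (0.79, adjusted p = 2.6e-05), and Lcn2, a secreted iron-binding protein (1.83, adjusted p = 2.7e-05), each higher with 4b in 6 of 6 pairs of groups, followed by Tgm2, a transglutaminase (0.44, adjusted p = 0.0045). The genes were chosen by the average over these same pairs, so the agreement of the pairs adds no support. In transgenic striatum Lcn2 was at 8.69 ± 1.25 with 4b and 6.75 ± 0.52 without (SD, n = 4 each), but in wild-type cerebellum at 9.46 ± 0.27 (SD, n = 4) and 8.62 ± 2.21 (SD, n = 3), where control 4 (11.17) lay above all 4 arrays with 4b. Within regions, averaged over genotypes, Lcn2 passed in striatum (limma adjusted p = 0.047) and 0 genes passed in cortex and cerebellum by limma (473 and 1352 at unadjusted p under 0.05). Of 100 splits 3 called as many genes as the real one, the highest other 105. This share would count against chance only if the arrays of the 3 regions came from separate mice, which the labels do not say. Each combination of genotype and treatment held the same numbers of males and females in the 3 regions, apart from wild-type control cerebellum. In 4b-treated transgenic mice these were 1 male and 3 females. Shared mice would give this, and the adjusted p-values here would then be too small. What set the split with 105 apart was not tested.

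The tables argue against several technical sources of the rise of Lcn2, Lrg1 and Vwf. With the BeadChip as a block all 3 kept an adjusted p of at most 5.5e-05, and without any single array at most 1.1e-04. More endothelium may raise Vwf, but the other 24 endothelial and mural genes had a median of 0.0379 (SD 0.121, highest 0.29), below the 0.62 of Vwf. Of these, 7 were higher and 1 lower at an unadjusted p under 0.05, among them Col4a2 (0.24), Pecam1 (0.18) and Ly6c1 (0.29), so a smaller rise of endothelium stays open as a part of the difference. More blood is argued against by a blood list median of -0.16, with Hba-a1, a globin, at -0.16. A share of neutrophils was not decided: S100a8, one of their abundant genes, had 0.63 (limma unadjusted p = 0.0406), but Camp had -0.20 (limma unadjusted p = 0.246), and with the BeadChip block Ltf (-2.59), Ngp (-2.13) and Elane (-1.37) were called lower with 4b in wild-type cerebellum. An inflammatory response of vessels to 4b or its vehicle stays open, and the labels do not say whether regions came from the same mice, in which case these p-values are too small.

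Of 82 measured genes of transcription factor families of embryonic patterning (Hox, Irx, Pax, Lhx and similar names, a choice made after the values of Hoxb5, Twist1 and others were seen) 18 rose and 2 fell in transgenic cortex, with a median of 0.02 over the 82, while 190 of all 614 called genes rose. A test of that share against all called genes was set aside as void, because the families were chosen from these values. In striatum 5 of 81 rose and 1 fell, and in cerebellum 1 of 83 rose. Besides Hoxb5 (3.41), the cortical rises included Hoxa7 (1.12), Dlx2, a factor of forebrain interneurons (0.93), and Hoxb2 (0.85).

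The background correction of dim probes could inflate such rises, but without it 18 of the 18 stayed called. Tissue of another region could bring such genes, but the granule neuron, Purkinje cell and thalamus lists had medians of at most -0.0887 in the same comparison, and no brainstem list had been fixed, so brainstem stays open. For the BeadChip a first test kept only 6 of 18 calls with it as a block, and there 17 of 18 were still higher with a median of 1.02 against 0.89 without, while the median SE went from 0.134 to 0.278. Both fits used the 16 cortical arrays, and the block alone raised the SE per unit of residual SD from 0.707 to 1.59. A further test, chosen after that result was seen, took 4b-treated arrays on shared BeadChips, where 18 of 18 were higher on each. One BeadChip held 1 transgenic and 1 wild-type array and the other 2 and 1, and genes of the same arrays are not replicates. The genotype itself stays open, and no mechanism was tested.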
